A study of Homo sapiens with 3 samples.

How the data were processed

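The series held 3 libraries of U-2932 cells, 1 each of AID ChIP, IgG ChIP and input. Per the labels' protocols, untreated cells in growth were fixed in formaldehyde at 1%, their chromatin was cut with MNase and by 60 min of sonication, the same amount of chromatin went into each immunoprecipitation, the AID antibody was diluted 1 in 2000, and libraries were sequenced on a NextSeq instrument. Per the submitters' processing notes, the tools named are CASAVA 1.4, fastp 0.19.5, BWA 0.7.17, Picard, SAMtools and MACS2 2.1.1, with the genome build hg19. Peak names in the deposited lists carry a tag that reads as marked duplicates. The control library, the threshold of the caller and the rule by which IgG artefacts were removed are not given in the sources used here. The input had no peak list of its own among the data used, and its reads were not analysed here. Because reads were not used, a site below the caller's threshold is missing from a list whatever its signal, and a change of depth would change the number of peaks.

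Each deposited list is in the broad peak format of the caller, with peaks called per library. The deposited score is a whole number close to 10 times -log10 q. The fold enrichment of a peak is a ratio made by the authors' caller, of the pileup to the local background. The deposited -log10 p and -log10 q are the caller's own. Fold and q were used to describe, rank and filter peaks within a list, never to compare AID with IgG heights. All columns with measurements were read.

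The main list was the AID list without IgG artefacts, with the list as called and the IgG list beside it. Groups came from the antibody given in the labels. Annotation used GENCODE 44 lifted to the GRCh37 build, which shares coordinates with hg19, for chromosomes 1 to 22 and X, so 4568 of 4573 peaks were annotated. Overlap meant at least 1 bp. Random placements (1000, or 100 for sequence) kept the width and chromosome of each peak and avoided assembly gaps. Peak midpoints were assigned, in this order, to promoter (within 1000 bp of a transcription start site), 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic. Starts of all annotated transcripts counted, so a promoter peak can lie far inside a gene. Expected peaks per chromosome were proportional to non-gap bases. A run was at least 50 peaks in a row with gaps of at most 100 kb, a rule added after the peaks had been seen. GC-matched windows had the width of the peak and a GC content within 1 percentage point; 36 of the 4568 peaks found no match. The local background of a peak was recovered by solving for the Poisson mean that gives both its fold and its p, with a pseudocount of 1. It is not an independent measurement, since peaks near the threshold tie it to the fold. Percentiles and ranges describe these libraries and are not tests between conditions, and no p-value is given.

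There were 22 gene lists: immunoglobulin gene segments, AID targets, lymphoma drivers, B-cell identity, NF-kB, DNA repair, DNA methylation and chromatin, cell cycle, histone, ribosomal protein, housekeeping, ZNF zinc-finger, HLA, T-cell, myeloid, epithelial, fibroblast and endothelial, liver, neuronal, olfactory receptor, fragile-site and nuclear mitochondrial genes. A member counted when a peak overlapped its gene body or 1000 bp upstream. Each count was placed among 10000 random lists of protein-coding genes of the same size matched on gene length in 20 bins. Immunoglobulin segments were counted without random lists. The lists, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the genes at or nearest to the 10 peaks of highest fold and the 5 widest, the 5 genes with most peaks and the 5 with most bases under peaks, up to 15 AID targets by fold, the immunoglobulin loci, up to 4 members of every other list and up to 5 genes under the highest IgG peaks. Some genes the rule covers are not reported here.

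Alternatives were a -log10 q of at least 2, a fold at or above the median, the AID list as called, other overlap rules, genome-wide placement, merging of peaks within 1000 bp, promoter windows of 2.5 kb or any overlap with the promoter, protein-coding genes alone, gene bodies with 5 kb on both sides, promoters alone, random lists matched on chromosome, windows of 250 kb, the central 500 bp of peaks and matching on GC. Leaving out the chromosome 3 run and matching lists on GC content were added after seeing the data. The planned share of repeat-masked bases was not run, because the reference used here carries no repeat masking; the uniqueness of 32-base words was used in its place.

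The steps were tested on simulated data. Recovered backgrounds lay within 5% of the true value for 298 of 298 simulated peaks. The simulated p came without noise from the formula that was then solved, so this checks the solver alone. How well the formula holds for the deposited peaks was not tested. With 20% of simulated peaks planted at promoters the promoter share was 27.3%, where 27.3% was expected once random promoter hits were added. The random hits were counted in the same draw and planted peaks were centred on start sites. The match was therefore fixed in advance, and it checks the class labels alone. Of 200 random gene lists 7 fell outside the central 95% range, and 20 of 20 lists of 40 genes with planted peaks lay above it among 19490 genes. Before planting, each simulated gene had the same chance of a peak, whatever its length or neighbours. The matching on length and the effect of clustered genes were therefore not tested. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, SAMtools 1.23.1 for indexing the genome, and matplotlib 3.10.9.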

Results

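Chromatin of untreated U-2932 cells, an established line of activated B-cell type diffuse large B-cell lymphoma, was immunoprecipitated with an antibody against activation-induced cytidine deaminase (AID) or with rabbit IgG, and an input library was made beside them. AID is the enzyme that deaminates cytosine in immunoglobulin genes during somatic hypermutation and class switching, and it also acts at other loci in B cells. The question was where AID lay on chromatin in cells growing without a stimulus. The 3 libraries comprised 1 per group, so there were no replicates, and nothing below compares conditions. Peaks had been called in each ChIP library separately. Reads per library were not given in the sources used here, so the depth is unknown. Fold enrichment and q of each peak are the authors' own values from the peak caller and are used within a list. Intervals are 95% exact Clopper-Pearson binomial intervals for shares and exact Poisson intervals for counts, and cover counting error only.

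AID ChIP gave many more enriched regions than IgG ChIP, and few places were enriched by both antibodies. The AID list held 4824 peaks over 5231 kb as called and 4573 peaks over 4795 kb after the authors had removed IgG artefacts, against 109 IgG peaks over 174 kb. Kept AID peaks were modest in height, with a median fold enrichment of 2.39 (quartiles 2.19 and 2.66) and a median width of 723 bp (quartiles 423 and 1271 bp), and 514 of them (11.2%) reached 3-fold. Of the 4824 AID peaks, 106 overlapped an IgG peak (2.20%, interval 1.80 to 2.65%), against a mean of 0.494 in 1000 random placements of the same widths on the same chromosomes (central 95% range 0 to 2). Seen from the other list, 102 of the 109 IgG peaks (93.6%) were overlapped by an AID peak. AID peaks on IgG peaks were low in fold, with a median of 1.83 against 2.39 for the others. When peaks below the median fold were dropped, 17 of the 106 overlaps were left. By q they were strong, with a median -log10 q of 11.9 against 2.06 for kept peaks. With -log10 q of at least 2, 104 of the 106 overlaps were left. All 106 were among the 251 peaks removed by the authors, and no kept peak overlapped an IgG peak.

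The protein-coding genes under the highest IgG peaks were MYO1D, an unconventional myosin (IgG fold 5.35), PMF1 with its readthrough gene PMF1-BGLAP (4.13), CDC27, a subunit of the anaphase-promoting complex (3.80), and NBEAL2, which acts in platelet granule formation (3.72). NBEAL2 had no AID peak. MYO1D kept 2 AID peaks elsewhere in the gene. The highest IgG peak of all lay on chromosome 12, from 127650474 to 127650987 (hg19, fold 10.24), at a promoter of a non-coding transcript. No member of any of the gene lists below lay under an IgG peak or under a removed AID peak.

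AID peaks were spread unevenly over the chromosomes, and a single dense run on the short arm of chromosome 3 held 532 of them. Counting the 4568 kept peaks of chromosomes 1 to 22 and X, chromosome 3 had 834 (18.3%), 2.66 times the number expected from its length (interval 2.48 to 2.84). The run stretched from 86715253 to 90303955 on chromosome 3, 3.59 Mb with 148 peaks per Mb, 762 kb of it under peaks. It covered VGLL3, a transcriptional cofactor (19 peaks), CHMP2B, a subunit of the ESCRT-III membrane-remodelling complex (5), POU1F1, a pituitary transcription factor (3), HTR1F, a serotonin receptor (31), CGGBP1 (14), ZNF654 (12), C3orf38 (1), CSNKA2IP (21) and EPHA3, an ephrin receptor (44). Most of the run was not in genes, with 66.7% of its peaks intergenic, 29.9% in introns and 2.26% at promoters. The fold varied little along it, with a median of 2.09 (quartiles 2.01 and 2.16, highest 2.65). Outside the run chromosome 3 held 302 peaks, 7.48% of the rest and 1.09 times expectation. The share of chromosome 3 was 10.8% among peaks with -log10 q of at least 2 and 4.95% among peaks at or above the median fold. IgG ChIP had 2 peaks on chromosome 3, both outside the run.

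**Figure D1:**
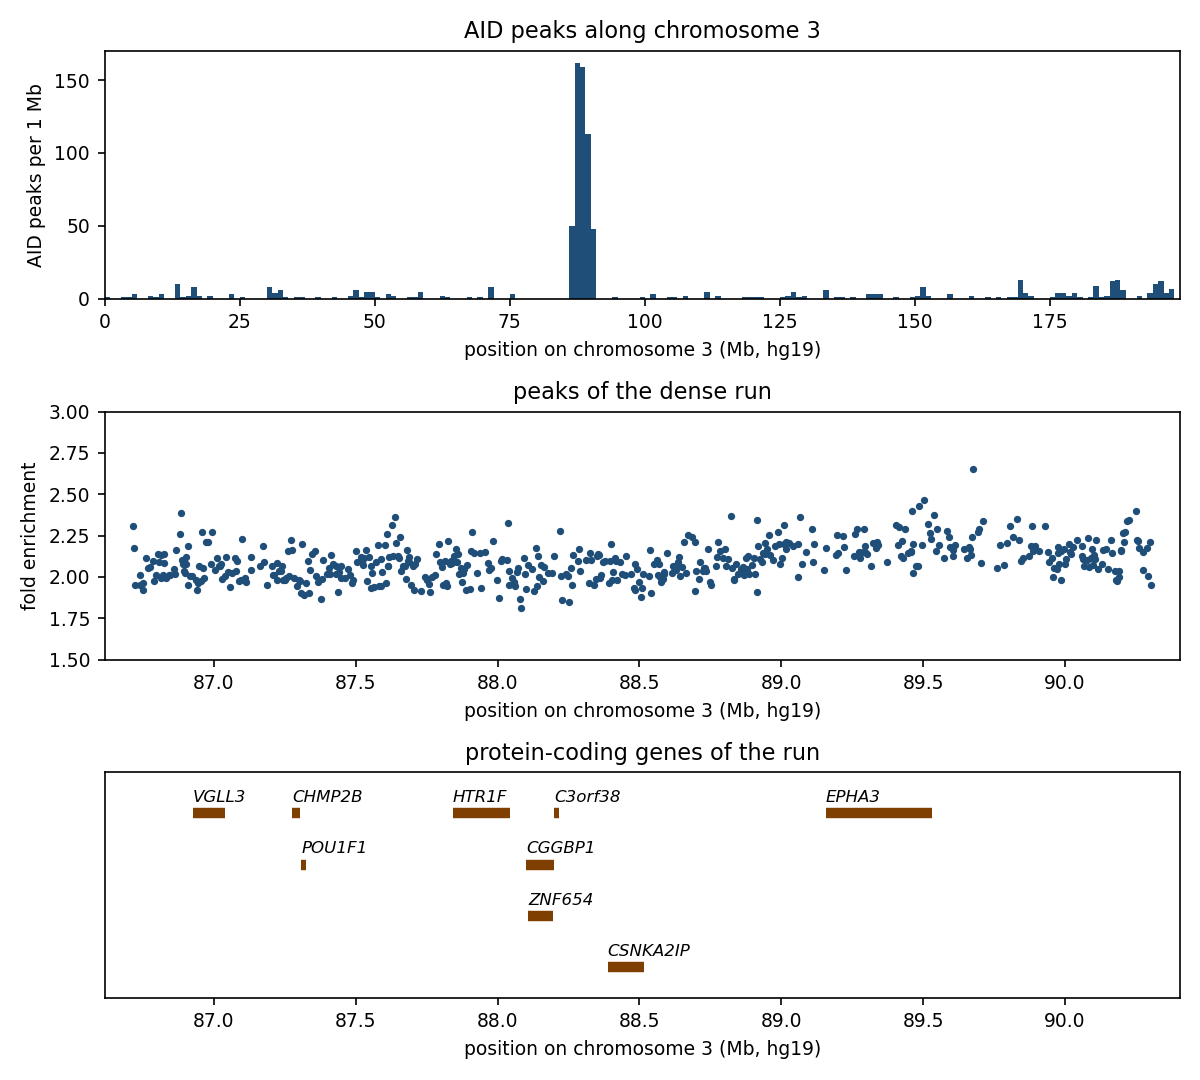
Kept AID peaks per 1 Mb along chromosome 3 (top, x axis in Mb of hg19, y axis the number of peaks), the authors' fold enrichment of each of the 532 peaks of the dense run (middle, 1 point per peak), and the protein-coding genes of the run (bottom, bars from gene start to gene end). The densest 1 Mb window holds 162 peaks, and the folds of the run lie near their median of 2.09 over its whole length.

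Besides chromosome 3, the excess was highest on chromosomes 22 (167 peaks, 2.97 times expectation, interval 2.54 to 3.46), 19 (234 peaks, 2.60, interval 2.28 to 2.96), 17 (245 peaks, 1.95, interval 1.72 to 2.22) and 16 (219 peaks, 1.72, interval 1.5 to 1.97). Chromosome 5 lay at 0.500 times expectation (143 peaks, interval 0.421 to 0.588) and chromosome X at 0.0945 (23 peaks, interval 0.0599 to 0.142). Expectation used length alone, not gene density or local background. Chromosomes 19, 17, 22 and 16 had 26.5, 15.3, 12.9 and 10.9 protein-coding genes per Mb, against 4.97 on chromosome 5 and 5.75 on X. Chromosomes 11 and 1, with 10.0 and 9.29, lay at 1.05 and 0.868 times expectation. The chromosome 3 run is part of the total and so lowers the ratio of every other chromosome. With the run left out, chromosomes 11 and 1 lay at 1.19 and 0.982 times expectation. Chromosomes 22, 19, 17 and 16 then lay at 3.36, 2.95, 2.21 and 1.95, chromosome 5 at 0.565 and X at 0.107. Chromosome X had the lowest median recovered background, 7.01 against 12.1 over all kept peaks. Neighbouring peaks lay closer together than placed at random, with a median distance of 50.05 kb against 334 kb, and 82.4 kb outside the run. The densest 1 Mb window outside the run, from 1 to 2 Mb of chromosome 7, held 25 peaks, while the highest window of any random placement held 16. The next were 2 windows of chromosome 16 with 23 peaks each, 85 to 86 Mb and 88 to 89 Mb. They were followed by chromosome 6, 0 to 1 Mb (22 peaks), and chromosome 22, 23 to 24 Mb (21). IRF8, a transcription factor of germinal centre B cells, lay in the first of these windows but had only 3 peaks itself. IRF4, a factor of plasma cell differentiation, lay in that of chromosome 6 and had 2. POU2AF1, the B-cell coactivator OCA-B, had 11 in a window of 18 (chromosome 11, 111 to 112 Mb). These genes were picked by name, and other windows as dense are not described.

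AID peaks lay at promoters more often than random placement gives. By the peak midpoint, 1120 of 4568 peaks (24.5%, interval 23.3 to 25.8%) lay within 1 kb of a transcription start site, against 8.59% in random placements (central 95% range 7.79 to 9.44%), a ratio of 2.85. Introns held 44% (interval 42.6 to 45.5%, random 53.4%) and intergenic sequence 27.0% (interval 25.7 to 28.3%, random 34.3%). Coding exons held 1.09% (random 0.886%) and 3' UTRs 1.71% (random 1.43%). Outside the chromosome 3 run promoters held 27.5% and intergenic sequence 21.8%. IgG peaks were distributed otherwise: 69 of 91 (75.8%, interval 65.7 to 84.2%) were intergenic and 11 (12.1%, interval 6.19 to 20.6%) lay at promoters, within the range of random placement (3.30 to 14.3%). Height and class were only loosely related, since the median fold in the list as called was 2.41 at promoters, 2.42 in introns, 2.60 in coding exons, 2.60 in 3' UTRs and 2.27 between genes. A promoter window of 2.5 kb raised the promoter share to 37.2%, and its ratio to random was then 2.08.

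**Figure D2:**
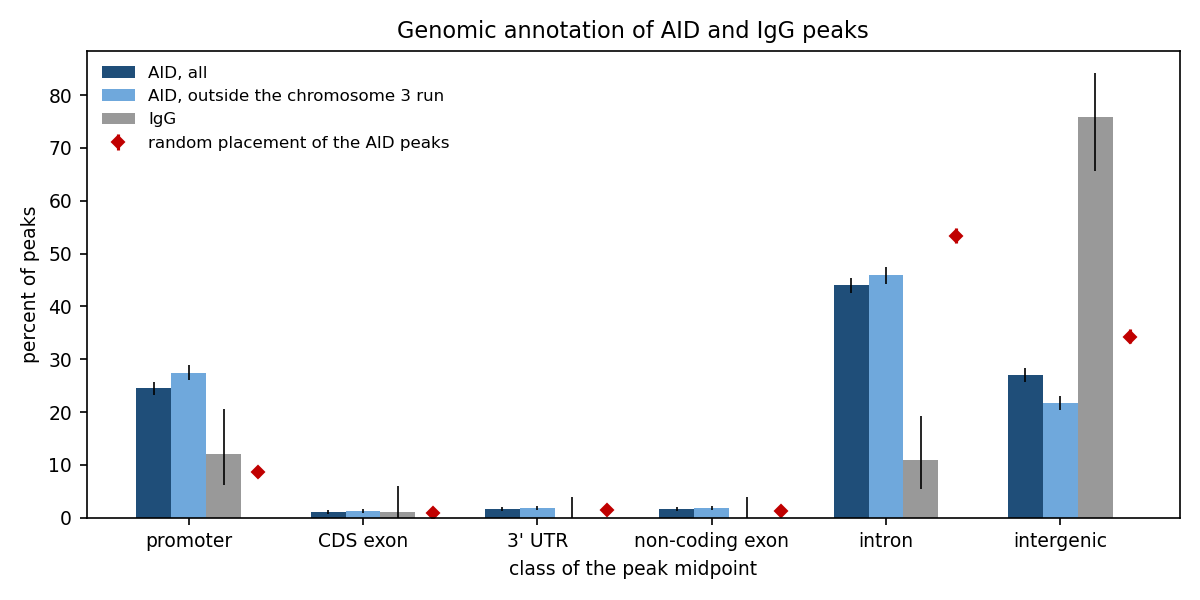
Percent of peaks (y axis) by class of the peak midpoint (x axis) for kept AID peaks, kept AID peaks outside the chromosome 3 run and IgG peaks, with 95% binomial intervals as error bars, and the mean of random placements of the AID peaks with its central 95% range as diamonds. AID promoter bars of 24.5% and 27.5% stand above the random 8.59%, and 75.8% of IgG peaks are intergenic.

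Of 19489 protein-coding genes, 1859 (9.54%) had an AID peak in the gene body or within 1 kb upstream, 528 had at least 2 and 67 at least 5. Genes with a peak were longer, with a median of 56.7 kb against 24.6 kb, so gene lists were set against random lists matched on gene length. The random lists were not matched on expression or open chromatin in these cells, so whether either accounts for the coverage of a list was not tested. The number of genes with a peak was 1220 for peaks with -log10 q of at least 2, 1196 for peaks at or above the median fold, and 958 when the peak had to lie at the promoter.

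Genes described as off-target sites of AID were among the most often covered. Of 41 such genes 21 (51.2%) had a peak, against 4.01 in random lists (central 95% range 1 to 8, percentile 100 of 10000 lists), and 15 had one at the promoter, against 2.0. Transcription factors of the B lineage led the list by fold. ETS1 had its highest peak in an intron (chromosome 11, 128340115 to 128341360, fold 3.07), IRF8 at a promoter (chromosome 16, 85941287 to 85942616, 2.90), PAX5, which maintains B-cell identity, in an intron (chromosome 9, 36993906 to 36994652, 2.81) and IRF4 at a promoter (chromosome 6, 390668 to 391022, 2.56). POU2AF1 carried 11 peaks over 18610 bp, the highest at a promoter (chromosome 11, 111247923 to 111251022, 2.84). The promoter peaks of IRF8 and POU2AF1 lay 9.23 and 76.9 kb from the gene start, near starts of further transcripts. DTX1, a ubiquitin ligase of Notch signalling, carried 6 (best 2.86), ST6GAL1, a sialyltransferase, 11 over 27797 bp (2.54), and OSBPL10, an oxysterol-binding protein, 7 (2.43). ZFP36L1, an RNA-decay factor, reached 2.84 at its promoter, CIITA, the transactivator of MHC class II genes, 2.56, BCL7A 2.54, the phosphatase DUSP2 2.44, LPP 2.34 with 6 peaks, and RHOH, a haematopoietic GTPase, 2.29. BCL6, PIM1 and SGK1, singled out after the values were seen, had none. Keeping peaks at or above the median fold left 13 of the 21. The best peaks of ST6GAL1 and LPP lay over recovered backgrounds of 27.6 and 29.4, against a median of 12.1 over all kept peaks. A peak over a high background passes the threshold at a lower fold, so peak numbers at these 2 genes are not comparable with those elsewhere.

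The 3 immunoglobulin loci were each covered by groups of peaks denser than their chromosomes. The heavy-chain locus IGH (chromosome 14, 106053226 to 107283280) held 17 peaks over 37 kb, 13.8 per Mb against 1.69 for the chromosome, with a best fold of 3.01. Of these, 8 lay in the span of the constant genes and 8 in that of the variable segments. The constant-region peaks included IGHM (106316446 to 106322360, fold 2.33), and a peak lay beside IGHJ6 (106327073 to 106330461, 2.58). The kappa locus IGK (chromosome 2, 89156674 to 90274235) held 10 peaks over 17.6 kb, 10.9 per Mb of sequence outside assembly gaps against 1.04, including a peak of 9948 bp at the constant gene IGKC (89150423 to 89160370, 2.40). IGK also held 6 of the removed AID peaks and 2 IgG peaks. The lambda locus IGL (chromosome 22, 22385332 to 23265206) held 21 peaks over 31.7 kb, 23.9 per Mb against 4.79, of which 16 lay among the variable segments, with a best fold of 3.50. By single segments, 22 of 212 immunoglobulin gene segments (10.4%) had a peak in the segment or within 1 kb upstream. This share was near the 9.54% of all protein-coding genes, a comparison not matched on length.

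B-cell identity and signalling genes had the highest coverage of all lists. Of 27, 17 (63.0%) had a peak, against 2.92 at random (range 0 to 6, percentile 100). They included the kinases LYN (chromosome 8, 56798125 to 56798407, intron, fold 3.11) and BLK (7 peaks, best 2.85), the adaptor BLNK (2.80) and EBF1, a factor that specifies the B lineage (2.67, 4 peaks). Genes recurrently altered in diffuse large B-cell lymphoma followed with 13 of 37 (35.1%, random 4.78, range 1 to 9, percentile 99.99). They included the transcription factor FOXO1 (chromosome 13, 41226158 to 41227270, intron, fold 3.12), the histone methyltransferase gene KMT2D (3.04, coding exon) and ETV6 (3.03). The list of NF-kB signalling genes as a whole had 4 of 24 (random 2.34, percentile 86.6), namely TRAF3 (3.03), RELB (2.77), the BAFF receptor TNFRSF13C (2.72) and CFLAR (2.29).

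Genes of DNA methylation and chromatin were also covered beyond random lists, with 12 of 31 (38.7%, random 3.86, range 1 to 8, percentile 100). SMARCA4, the ATPase of the BAF remodelling complex, had a promoter-class peak on chromosome 19 from 11132247 to 11133047 at fold 5.38 and with the highest -log10 q of the kept list, 60.9. That peak lay 61.0 kb from the gene start, near the start of a further transcript. The DNA demethylase TET3 reached 3.53 and SUZ12, a subunit of the Polycomb repressive complex, 2.89. Histone genes had 30 of 71 (42.3%), against 2.60 in lists matched on length (range 0 to 6) and 15.3 in lists matched on chromosome as well (range 11 to 20). All 30 lay on chromosome 6, between 26020714 and 27863222, under 22 peaks with a median fold of 2.38, and random lists do not copy the closeness of these genes to each other. H3C3 (3.53), H1-2 (3.0), H3C12 (2.95) and H1-4 (2.74) had the highest peaks.

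Lists of general cell functions lay within the random range. DNA repair genes had 5 of 33 (random 4.23, percentile 66.9), among them the checkpoint kinase CHEK2 (2.71), the mismatch repair gene MSH6 (2.52) and NBN (2.51). Cell-cycle genes had 3 of 23 (percentile 83.3), namely MCM5 (2.48), CCNE1 (2.25) and E2F1 (2.23). Ribosomal protein genes had 6 of 84 (percentile 81.0), the highest at RPS6 (2.60), RPS14 (2.34), RPS19 (2.11) and RPS29 (2.06). Housekeeping genes had 1 of 20, EEF1A1 (2.13, percentile 36.9), nuclear genes of mitochondrial proteins 1 of 13, NDUFB5 (2.03, percentile 54.9), HLA genes 1 of 19, HLA-C (2.33, percentile 55.6), and very long genes at fragile sites 2 of 14, CTNNA3 (2.86) and IMMP2L (2.14, percentile 33.8).

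Genes of other cell types lay within the random range, except olfactory receptor genes, which lay below it. T-cell genes had 1 of 15, LCK, the kinase of T-cell receptor signalling, with a peak upstream at fold 4.01 (chromosome 1, 32713746 to 32716740, percentile 46.3). Epithelial genes had 1 of 11, MUC1 (2.39, percentile 51.5), and neuronal genes 2 of 11, TUBB3 (2.75) and RBFOX3 (2.67, percentile 71.5). Myeloid genes had 0 of 12 (percentile 25.9), fibroblast and endothelial genes 0 of 11 (14.5) and liver genes 0 of 11 (20.02), lists too short for a count of 0 to leave the random range. Olfactory receptor genes had 0 of 399, below every random list matched on length (mean 16.1, range 9 to 24). Zinc-finger genes of the ZNF series had 30 of 515 (5.83%), fewer than in nearly all random lists (46.7, range 35 to 59, percentile 0.38), with the highest peaks at ZNF335 (3.51), ZNF595 (3.08), ZNF341 (3.0) and ZNF578 (2.77).

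**Figure D3:**
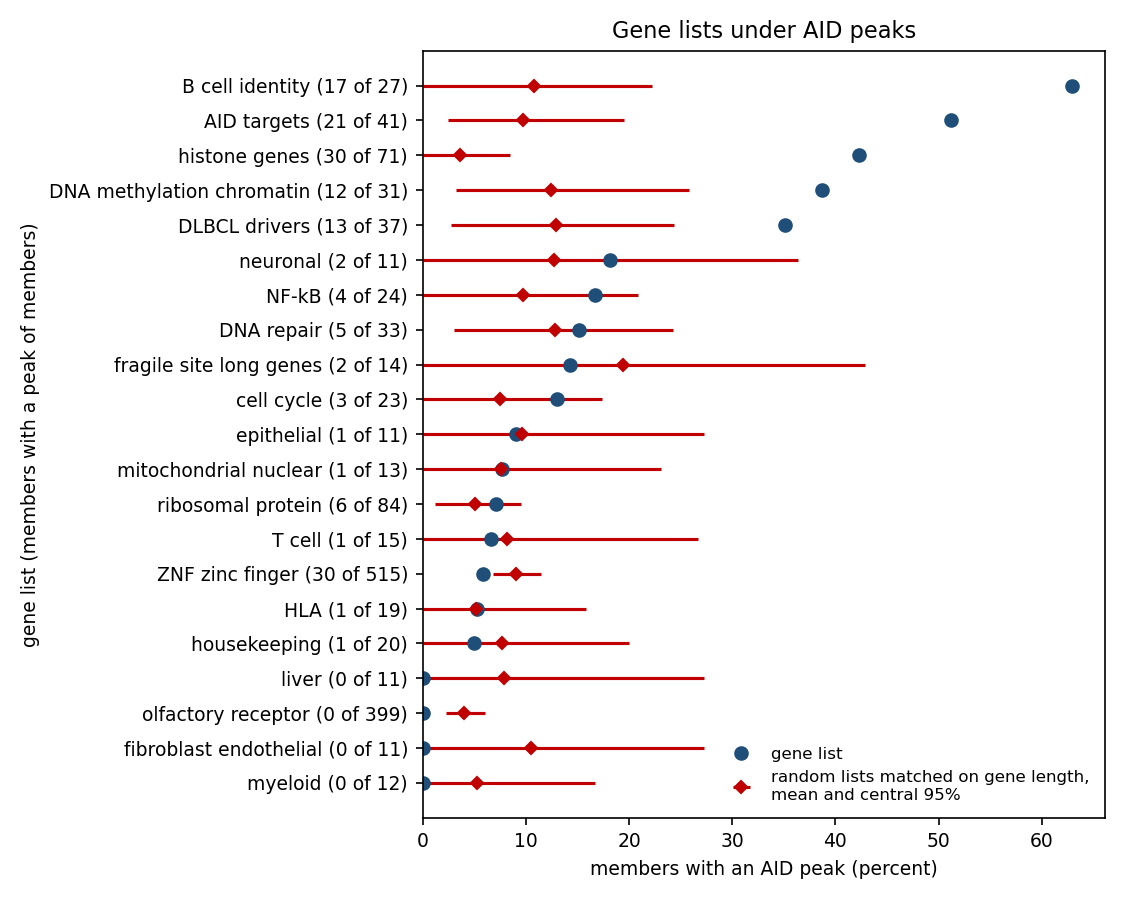
Percent of the members of each gene list with an AID peak in the gene body or within 1 kb upstream (x axis, blue points) beside the mean and central 95% range over 10000 random lists matched on gene length (red diamonds and lines), with the lists on the y axis. B-cell identity genes (63.0%), AID targets (51.2%), histone genes (42.3%), chromatin genes (38.7%) and lymphoma drivers (35.1%) lie to the right of their ranges, and ZNF and olfactory receptor genes to the left.

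On the long arm of chromosome 18 AID peaks were low. Between 50 and 65 Mb there were 92 peaks (6.13 per Mb, 173 kb) with a median fold of 1.56, against 2.22 for the 73 peaks on the rest of the chromosome. The stretch was bounded by joining 5 Mb windows with a median fold under 1.7, so this contrast follows from the choice. BCL2, the anti-apoptotic gene, had more bases under peaks than any other gene, 64916 bp in 10 peaks, yet its best fold was 1.96. Its widest peak (chromosome 18, 60848085 to 60865223, intron) spanned 17139 bp, the widest of the list, at fold 1.7. TCF4, the transcription factor E2-2 of B-cell and dendritic cell development, had 15 peaks with a best fold of 1.84. The local background, recovered from the fold and p of each peak, had a median pileup of 109.6 in this stretch against 14.9 on the rest of chromosome 18 and 12.1 over all kept peaks. A peak over a high background passes the caller's threshold at a lower fold, so these folds and backgrounds are tied to each other.

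**Figure D4:**
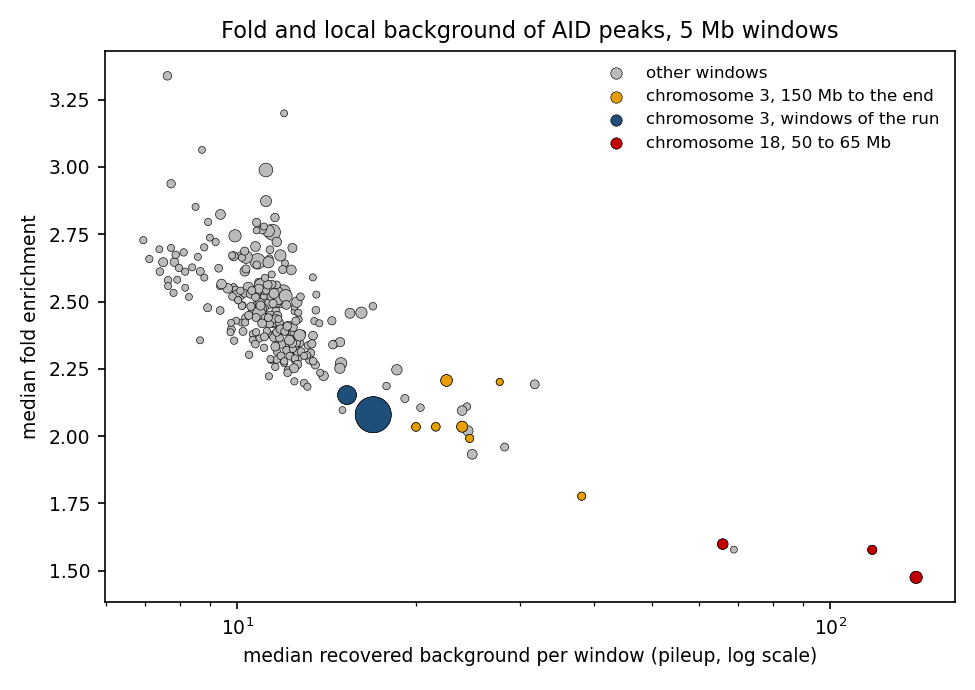
Median fold enrichment (y axis) against the median recovered background pileup (x axis, log scale) of the kept AID peaks in 5 Mb windows, with point area growing with the number of peaks. Red windows of chromosome 18 (50 to 65 Mb) lie at high background and low fold, with a grey window of 5 peaks on chromosome 13 (95 to 100 Mb, background 68.8, fold 1.58) among them, blue windows hold the dense run of chromosome 3, orange windows the end of chromosome 3.

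The 10 highest AID peaks had folds from 5.87 to 8.32. The peak of highest fold was at the promoter of ATAD3C, of a family of mitochondrial ATPases (chromosome 1, 1397964 to 1398398, fold 8.32). Others were 8.98 kb from TRAPPC11, a gene of vesicle transport (chromosome 4, 184643732 to 184644797, intergenic, 8.21), 1.5 kb from IQCN (chromosome 19, 18365799 to 18366410, 7.29), and in an intron of the nucleotidase ENTPD6 (chromosome 20, 25200721 to 25201285, 7.28). A coding exon of the kinase gene CDC42BPG (chromosome 11, 64597136 to 64597554, 6.59) and an intron of CBFA2T3, a transcriptional corepressor of blood cells (chromosome 16, 89033673 to 89035831, 6.54), came next. The remaining 4 of the 10 lay in introns of the non-coding gene EPIC1 (6.23) and of the potassium channel gene KCNN3 (6.04), 4.54 kb from RIN1 (5.91) and 8.89 kb from YWHAZ (5.87). Among the 5 widest peaks, besides BCL2 with 2 and IGKC with 1, were 16956 bp next to IGKC (chromosome 2, 89129705 to 89146660, fold 2.58) and 10469 bp near ZCCHC7 and LINC01627 (chromosome 9, 37374565 to 37385033, 2.46).

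Sequence under the AID peaks was richer in GC and in the motifs AID prefers than random placements. Mean GC was 48.8% against 41.7% (range of 100 placements 41.4 to 41.9%), and observed over expected CpG 0.324 against 0.216. The hotspot WRC/GYW (W is A or T, R is A or G, Y is C or T) occurred 11.6 times per 100 bp against 10.8 (ratio 1.07), WRCY/RGYW 6.75 against 6.30 (1.07), and AGCT, the motif frequent in switch regions, 0.560 against 0.454 (1.23). Against windows matched on GC the ratios were 1.05, 1.02 and 1.1. The cold spot SYC/GRS (S is C or G) was also more frequent than at random, 14.3 against 10.7 per 100 bp (1.34), but lay below windows matched on GC, at 0.974. In the chromosome 3 run the peaks were poor in GC (33.3% against 39.7%), and the 3 hotspot motifs lay at 0.999, 0.991 and 0.991 times GC-matched windows. IgG peaks had 43.3% GC and 0.235 AGCT per 100 bp, 0.519 times random placement.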

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

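The comparison of positions with assembly gaps was chosen after the peaks had been seen. The authors removed 251 AID peaks as IgG artefacts, and 145 of these overlapped no IgG peak of the deposited list. They stood out because the removed peaks were not part of the main comparisons and more than the overlap with IgG was taken away. Their median fold was 2.13 and their median recovered background 19.4, against 1.83 and 117 for the 106 removed peaks that did overlap IgG. Within 5 Mb of the longest assembly gap of their chromosome, the centromere on most, lay 136 of the 145 (93.8%), 71 of the 106 overlapping ones (67%), 72 of the 109 IgG peaks (66.1%) and 779 of the 4573 kept peaks (17.03%). The 779 comprised all 532 peaks of the chromosome 3 run and 247 of the 4041 others (6.11%). Of sampled 32-base words, 59.4% in removed peaks and 58.0% in IgG peaks occurred once in the genome, against 86.2% in kept AID peaks outside the run.

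There were 7 IgG peaks that overlapped no AID peak as called, a signal of the control antibody in places the AID list does not reach. NBEAL2, with an IgG fold of 3.72, was the gene under 1 of them.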

How the results depend on the processing

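Leaving out the chromosome 3 run was chosen after the result was seen. Over 71 alternatives of 14 main results 25 stayed within their interval, or within 1.5 times for a count, and 46 moved. For counts, shares of peaks and the ratios of those shares to random, the labels held no change of direction, so none could be recorded. The promoter and intergenic ratios printed below kept their side of 1. Of 193 other values 170 stayed, 21 moved, 1 weakened and 1 reversed. These 193 include 168 gene list percentiles, of which 167 stayed and 1 weakened. Nearly all other values of different kinds moved. Gene list percentiles kept their side of the central range in 167 of 168 cases; the exception was ZNF genes counted by promoter alone (percentile 3.76). Where a threshold removed peaks, counts fell by construction; elsewhere the cause was not tested. With -log10 q of at least 2 there were 2399 peaks, 10.8% on chromosome 3, 23.6% intergenic (0.686 of random), 34 in the densest window, 1220 genes with a peak, 51.5% GC and 11.9 WRC/GYW per 100 bp. With fold at or above the median there were 2287 kept peaks (of the 2412 in the list as called, 17 overlapped IgG peaks), 4.95% on chromosome 3, 25.9% at promoters, 21.3% intergenic (0.619 of random), 22 in the densest window, 13 AID targets, 1196 genes, 52.7% GC and 11.9 WRC/GYW. In the list as called, 29.9% were intergenic, GC was 48.3% and WRC/GYW 11.4, as in the central 500 bp (48.3% and 11.4). Without the run, 7.48% lay on chromosome 3, 27.5% at promoters, 21.8% were intergenic (0.629 of random), the densest window held 25, GC was 50.8%, WRC/GYW 11.7, and the median fold of promoter over intergenic peaks 1.02 (1.06 with it, 1.04 in the list without IgG artefacts). A promoter window of 2.5 kb gave 37.2% promoter (2.08 of random) and 24.5% intergenic (0.755). Protein-coding genes alone gave 18.4% (3.47) and 39.0% intergenic, any overlap with the promoter 29.3%, and genome-wide placement 3.23 and 0.738. Windows of 250 kb held at most 46, and 958 genes had a promoter peak. Matching on GC lowered the WRC/GYW ratio from 1.07 to 1.05 and reversed SYC/GRS from 1.34 to 0.974. The cold spot is itself rich in G and C, and why it fell below matched windows was not tested. Merging peaks within 1000 bp changed nothing, as no neighbours lay that close, and says nothing on stability. The planned share of repeat-masked bases was not run. No paired analysis was possible because each group had 1 library. Depth is unknown, so how many weak sites were missed cannot be stated.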

Other observations

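The tests on copy number, GC content and IgG in the chromosome 3 run, both tests on chromosome 18, and the genes of the next paragraph were chosen after the result was seen. Apart from AID following the genes of the chromosome 3 run, no biological explanation was tested for these patterns.

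Further genes had many AID peaks or many bases under them. MCL1, an anti-apoptotic relative of BCL2, had 15953 bp under 4 peaks (best fold 1.89). PLCG2, the phospholipase activated by the B-cell receptor, had 16337 bp under 9 peaks (2.51). PITPNM2, a phosphatidylinositol transfer protein, had 11 peaks (2.80) and GSE1 had 12 (3.70). Of the B-cell identity genes, SPIB (2.61), TCF3 (2.55), SYK (2.45, 3 peaks), IKZF3 (2.37, 3 peaks) and CD38 (2.44) also had peaks, and MS4A1 and CD40 had none. Of the lymphoma drivers, MEF2B (2.80, 3 peaks) and KLHL6 (2.65, 4 peaks) had peaks, and EZH2, MYD88 and CREBBP had none. MCL1 and KLHL6 lay in 5 Mb windows of high median recovered background. It was 24.9 on chromosome 1 from 150 to 155 Mb and 24.6 on chromosome 3 from 180 to 185 Mb, against 12.1 over all kept peaks.

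In the heavy-chain locus, 6 of the 8 peaks in the constant span lay between 106143751 and 106173733 on chromosome 14, at or downstream of IGHA1 in the direction of its transcription, where a 3' regulatory region of the locus is known to lie. The widest of them ran from 106151071 to 106158297 (fold 2.57). In the lambda locus the highest peak at the end of the J and C segments ran from 23227086 to 23230241 on chromosome 22 (3.19), near IGLV3-1.

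The dense run of AID peaks on chromosome 3 ended at 90303955, short of the centromeric assembly gap that begins at 90504855, and so lay in the kind of region where most IgG and removed AID peaks lay. Repeated sequence is argued against, since 94.9% of sampled 32-base words of its peaks occurred once in the genome (random 88.4%), and so is GC content, since 4639 windows of 100 kb elsewhere with the same GC content held 0.184 times the peaks per Mb of all windows outside the run (exact Poisson interval 0.152 to 0.219). AID following the genes there is argued against by the 25.2% of its peaks inside protein-coding genes, within the range of random placement inside the run (23.5 to 31.4%). Copy number stays open: the densest 5 Mb window of the run held 11 times the peaks of the densest of 24 other windows with at least as high a background (96.8 against 8.80 per Mb), but the run was picked for its density, and a copy-number difference from the control library, which might raise a whole region, was not tested. IgG had 0 peaks inside the run and 2 on the rest of chromosome 3, too few to decide.

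For the low peaks on chromosome 18 between 50 and 65 Mb, around TCF4 and BCL2, repeated sequence is argued against as the cause. Of sampled 32-base words 82.6% occurred once (random 88.9%) and 13.04% over 10 times (random 5.87%), but the 58 peaks whose sampled words all occurred once had a median fold of 1.56 (quartiles 1.46 and 1.64), against 1.56 for the other 34 and 2.22 on the rest of the chromosome. The contrast with the rest of the chromosome follows from choosing the stretch by its fold. That between the 58 and the 34 peaks does not. A copy-number gain shared by AID chromatin and background may underlie the pattern and stays open. Of the 92 peaks 97.8% had a recovered background over 2 times the median of all kept peaks, and the median was 9.07 times as high. A low fold passes the threshold only over a high background, so this share follows from the low folds and decides nothing.

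The excess of AID peaks at promoters might follow from GC content. Windows matched on GC and width reached 15.4% at promoters, above the 8.59% of random placement, yet the observed share of the same peaks was 1.56 times as high (range 1.49 to 1.66), which argues against GC as the whole cause. Promoters made up 27.5% of peaks outside the chromosome 3 run (random 8.83%, range 7.98 to 9.71%), and the run, poor in promoters, could only lower the share. Open chromatin at promoters, which another antibody could pull down as well, was not tested.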
